A study of Mus musculus with 8 samples.

How the data were processed

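mRNA libraries of 8 mouse samples were analysed from the deposited tables. Per the labels' protocols, lineage-negative bone marrow cells were enriched with a progenitor enrichment kit, transduced or, for NT, labelled as not, treated with ethanol or OHT for 72 h, and made into libraries with a TruSeq RNA kit, which does not mark the strand. The groups come from the labels: a context (NT, HOXA9, PML-RARa or MLL-AF9) and a genotype, Ring1b WT (control) or Ring1b KO (OHT), with 1 library in each. The NT table heads its columns with a word for an empty condition and was matched to the samples labelled NT, whose name the table carries. TopHat, DESeq and the genome build mm9 are named in the submitters' processing notes, with no version and no order of use. The read counter, its annotation and any removal of repeat reads are not given in the sources used here.

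There are 4 deposited tables, 1 per context, each with 19353 RefSeq transcripts under 17551 symbols. Per the file headers, the signal columns hold the authors' normalised read count (base mean) of each transcript in each library. The ratio column, per the file headers, is the authors' fold change, OHT value over control value. The log2 column is the log2 of that ratio, also as deposited by the authors. The p-value column is deposited by the authors without adjustment and compares 1 library with 1 library, so it speaks of those libraries and not of the conditions; a Benjamini-Hochberg adjustment was added here. Of the symbols, 35 had been turned into dates and were restored through the RefSeq identifier, and 1509 symbols have several transcripts.

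The values of each library are whole multiples of its lowest value. Dividing by that step gave whole reads for 100% of the values (within a tolerance of 0.02), with a lowest entry of 1 and no 0. The steps match size factors computed jointly over the 8 libraries by the median of ratios (largest relative difference 4.7e-10). The design had assumed tables normalised separately; since they were scaled together, levels are set side by side across contexts, while every test still uses differences within a pair. From 15.1% to 20.0% of the transcripts stand at the lowest entry in a library, and whether an entry of 1 stands for 0 or 1 read is not known. Totals of recovered reads run from 4226751 to 6998223 per library. Reads per transcript level off below about 2 per base of transcript length: 1 of 18873 transcripts with a known length exceeds 2 in any library, 402 exceed 1 and 2046 exceed 0.5. The ratios of very abundant transcripts, such as Cpa3 (1.96 reads per base at most) and Eef1a1 (1.68), can therefore be compressed. They can also be shifted, because the size factor was lower in the OHT library of every pair. It was 0.962 against 1.21 in the control library of NT and 1.11 against 1.20 in HOXA9. In PML-RARa it was 0.840 against 1.05, and in MLL-AF9 0.733 against 0.944. A transcript held at the ceiling in both libraries would thus appear higher with OHT in all 4 contexts. Genes with several RefSeq transcripts had few reads, with a median of 7.40 per kb against 39.3 for genes with a single one, so genes such as Kit (1 to 29 reads) were measured poorly. Transcript lengths and current names came from the reference annotation, of which no coordinates are used.

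Because the values are normalised, the chosen test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), two-sided, with the context as a block, a constant prior variance and no robust option, over 10599 transcripts with a mean value of at least 20. Calls have a Benjamini-Hochberg adjusted p under 0.05. The test needs a change shared by the contexts, which serve as replicates. The same fit was made for the 3 transduced pairs, and the 4 ratios were compared between NT and the others. A ratio on the log2(value + 1) scale understates the change of transcripts with low values. edgeR (4.0.16, quasi-likelihood) on the recovered reads called 2235 transcripts across the 4 contexts, and DESeq2 (1.42.0) on the same reads called 3130. Within a context there is no replicate and no test: transcripts at least 2-fold apart with a value of at least 20 in the higher library were counted.

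The 21 gene lists, the rule for the genes named, the tests and most alternatives were fixed before the data were examined. The lists are PRC1 and PRC2 subunits, Hox genes, developmental transcription factors outside blood, germline and meiosis genes, cell cycle inhibitors of the INK4/ARF and CIP/KIP families, p53 targets, the HOX/MEIS leukaemia programme, stem and progenitor genes, neutrophil genes, monocyte, macrophage and dendritic cell genes, erythroid and megakaryocyte genes, mast cell, basophil and eosinophil genes, B, T and NK cell genes, stromal, endothelial and epithelial genes, proliferation genes, ribosome biogenesis genes, the BCL2 family, interferon response genes, cholesterol synthesis genes, and genes of the introduced fusions and of HOXA9. Some genes, such as Bax and Hoxa9, are in more than 1 list. Lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the lists. Within a context, a list's median was ranked among 10000 random lists of the same size matched on mean expression. Members low in the control library enter this ranking only if the OHT library is high, which the matching does not remove.

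Genes were named by rule: Rnf2, Ring1, Cdkn2a, Hoxa9 and Meis1 always; the 15 largest rises and 15 largest falls past the test with the same sign in all 4 contexts; the 5 largest each way in the transduced contexts; the 5 each way with the smallest p for the difference; the 8 highest and 8 lowest ratios within each context among transcripts with a value of at least 100 in the higher library; and 2 to 4 members of each list. Some transcripts that meet these rules are not reported here. A further few list members named were chosen after their values were seen. Near-identical paralogues, such as Bcl2a1a and Bcl2a1b, Ccl8 and Ccl12 or H2 genes, and overlapping or antisense genes can share reads in ways that counts cannot resolve.

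The tests were tried on simulated reads with 200 changed transcripts of 10599. For the fits across contexts, a changed transcript had the same fold in each context, and the dispersion was common to all transcripts. The shares recovered therefore do not apply where the change differs between contexts. The limma fit across the 4 contexts recovered 38% of 2-fold and 100% of 4-fold changes, with 7 false calls among 145, and edgeR recovered 49% and 100%, with 7 false calls among 156. Camera recovered 1 of 1 changed list and called 0 of the 20 unchanged ones. The simulated reads were drawn independently for each transcript, so members of a list did not vary together. The camera result therefore gives no rate of false calls for the real lists. Alternatives covered the pseudocount (0.5 and 10), the minimum value (none and 100), the scaling (centred ratios and TMM), a mean-variance trend, the block, edgeR and DESeq2, and leaving out each pair. Added after seeing the data were edgeR without each pair or with 1 read subtracted, leaving out transcripts over 0.5 reads per base, a correction for the ceiling of 2 reads per base, 1 transcript per symbol, the NT and MLL-AF9 pairs alone, and a minimum value of 100 between control libraries. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.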

Results

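RNA was sequenced from mouse lineage-negative bone marrow cells, a preparation from which mature blood cells have been depleted and in which haematopoietic stem and progenitor cells are enriched. The labels give the C57BL/6 donor mice as knocked out for Ring1 (also called Ring1a) and for Cdkn2a, the INK4A/ARF tumour suppressor locus. Ring1a and Ring1b, the product of Rnf2, are the alternative ubiquitin ligases of the Polycomb repressive complex PRC1, which represses developmental genes. The cells were treated for 72 h with ethanol or with 4-hydroxytamoxifen (OHT), and the labels give the treated cells as Ring1b KO and the others as Ring1b WT. The 4 contexts were cells labelled as not transduced (NT), and cells transduced with the homeobox gene HOXA9 or with the leukaemia fusion genes PML-RARa or MLL-AF9. The deposited NT table heads its columns with a word for an empty condition, so an empty vector in the NT cells is not excluded, and the 3 contexts with an introduced gene are called transduced here. Each of the 8 libraries is the sole library of its context and genotype, and the 2 libraries of a context form a pair. Read totals in the control libraries (labelled WT) were 6998223 in NT, 6657911 in HOXA9, 5992257 in PML-RARa and 5342836 in MLL-AF9. The OHT libraries (labelled KO) held 5699203, 6641843, 4886703 and 4226751 reads in the same order. At these depths 100 reads carry a 95% Poisson interval of 81.4 to 122, which covers counting error alone. Values are normalised read counts per RefSeq transcript of the mouse build mm9, and ratios are OHT over control on the log2(value + 1) scale.

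Rnf2, the gene deleted by the design, did not fall at the level of the whole transcript. Its value (NM_011277) went from 666 to 802 in NT, from 896 to 856 in HOXA9, from 990.4 to 771 in PML-RARa and from 769.8 to 767 in MLL-AF9. The mean log2 ratio was -0.04 ± 0.14 (SE over 4 contexts, limma adjusted p = 0.85). The labels do not say which part of Rnf2 is removed, and a whole-transcript count can keep reads from the rest of the gene, so this value checks neither label and the libraries are named by treatment here. Reads at Ring1 (NM_009066) were present in every library although the labels give the gene as knocked out, and they fell with OHT, from 109 to 43.6 in NT, from 191 to 47.1 in HOXA9, from 179.9 to 23.8 in PML-RARa and from 166 to 77.8 in MLL-AF9. That is a mean log2 ratio of -1.81 ± 0.33 (limma adjusted p = 0.040, 0.057 with no filter on low values and 0.090 to 0.11 without any 1 pair). The Cdkn2a transcripts NM_001040654 and NM_009877 had mean log2 ratios of 0.59 ± 0.21 (limma adjusted p = 0.11) and -0.38 ± 0.20 (limma adjusted p = 0.24), and values of 18 to 67.2 in the 8 libraries, so reads were present in every library at this gene too, which the labels give as knocked out. Hoxa9 (NM_010456) stood at 250 in the HOXA9 control library and 122 in the MLL-AF9 control library, against 20.7 in NT and 23.9 in PML-RARa. Its mean log2 ratio with OHT was -1.21 ± 0.37 (limma adjusted p = 0.086). The Hoxa9 ratio was -1.58 in NT, 0.01 in HOXA9, -2.11 in PML-RARa and -1.14 in MLL-AF9. Without the HOXA9 pair the mean was -1.61 ± 0.24 (limma adjusted p = 0.068). Meis1, a cofactor of HOX proteins, had ratios of 1.60, -1.01, 1.67 and -0.08 in NT, HOXA9, PML-RARa and MLL-AF9.

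The first comparison asked which transcripts changed with OHT in common to the 4 contexts. Among the 15 transcripts with the largest rise were the interferon-induced antiviral genes Rtp4 (5.96 ± 0.88, mean log2 ratio ± SE), Ifit3 (5.96 ± 0.82), Ifit1 (5.38 ± 0.59), Oasl1 (5.16 ± 0.71), Rsad2 (5.15 ± 0.70) and Usp18 (4.98 ± 0.82). Beside them were the scavenger receptor Marco (5.63 ± 0.78), the sialic acid receptor Siglec1 (5.28 ± 0.61), the complement subunits C1qa (5.17 ± 0.70) and C1qc (4.86 ± 0.80) and the monocyte-attracting chemokines Ccl8 (5.40 ± 1.01) and Ccl12 (5.10 ± 0.77). Atp6v0d2, a proton pump subunit (5.90 ± 0.94), Fabp4, a fatty acid carrier (5.23 ± 0.94), and Qpct (5.19 ± 0.55) complete the 15.

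The largest falls were those of Lct (-4.01 ± 0.69), Epx, the peroxidase of eosinophil granules (-4.00 ± 0.27), Ttc21a (-3.69 ± 0.30), Lcn4 (-3.19 ± 0.38) and Bpifc (-3.04 ± 0.67). Epx fell from 662 to 30.1 in NT, from 481 to 23.5 in HOXA9, from 373 to 19.0 in PML-RARa and from 826 to 98.2 in MLL-AF9. Also among the 15 largest falls were Lin28a, an RNA-binding protein that blocks let-7 maturation (-2.78 ± 0.44), and Birc5, or survivin, which acts in chromosome segregation (-2.61 ± 0.33). They also include the copper transporter gene Atp7b (-2.91), Slc44a4 (-2.75), 1810008I18Rik (-2.74), Smim6 (-2.71), Wdr65 (-2.64), Ccdc18 (-2.60) and Nebl (-2.59). The transcripts named here as the largest rises and falls were picked for passing the test with the same sign in all 4 contexts. Their limma adjusted p lay between 0.035 and 0.050.

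**Figure D1:**
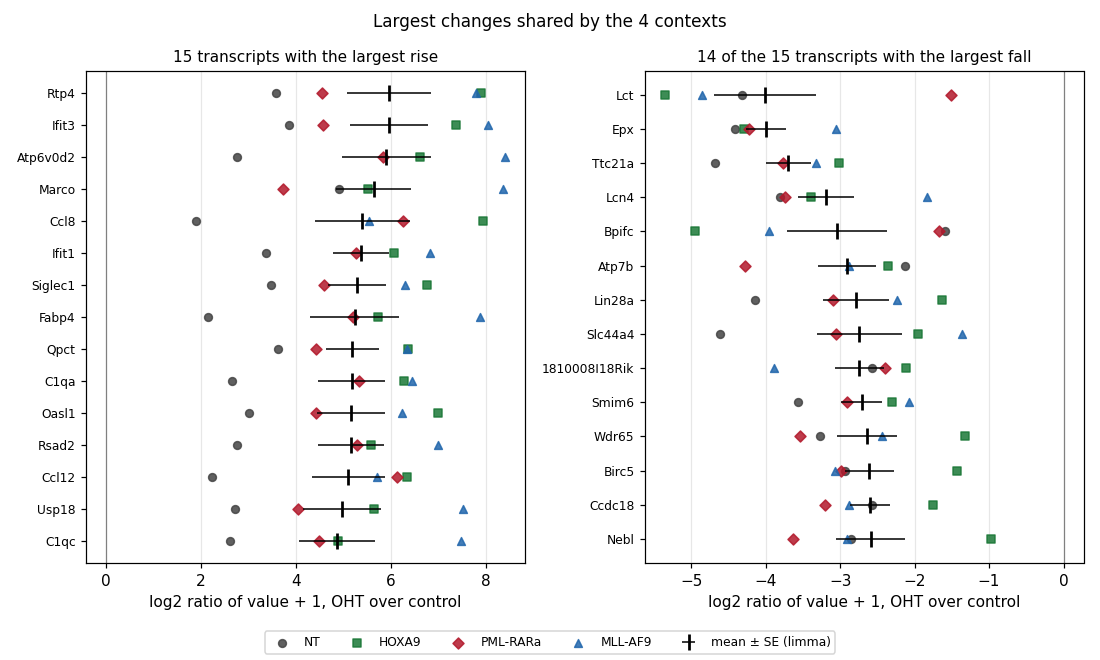
Log2 ratio of value + 1, OHT over control, for the 15 transcripts with the largest rise (left) and 14 of the 15 with the largest fall (right); coloured points are the 4 contexts, and black marks with bars are the mean and its SE from limma. The NT ratio is the smallest of the 4 for Rtp4 (3.59) and Ccl8 (1.89), while for Ttc21a the NT ratio (-4.68) is the farthest from 0.

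By limma with the context as a block, 1471 of 10599 transcripts with a mean value of at least 20 passed an adjusted p of 0.05. Of these, 678 were higher and 793 lower with OHT. All 1471 had the same sign in all 4 contexts, which a call from 4 pairs nearly requires. The contexts are the only replication, so each p measures the spread between contexts, and the calls rest on having all 4: limma called 26 without the NT pair and 0 without the HOXA9, PML-RARa or MLL-AF9 pair (3319, 3089 and 2982 at an unadjusted p under 0.05), where edgeR called 534, 512, 0 and 0. The smallest limma adjusted p was 0.048 without NT, 0.056 without HOXA9, 0.099 without PML-RARa and 0.079 without MLL-AF9. All 1471 kept their sign and an unadjusted limma p under 0.05 in each of these fits. The fits reuse the pairs by which the 1471 were chosen, so this is no independent check. edgeR on the recovered reads called 2235 with all pairs, 57.1% of them higher against 46.1% by limma, and 1376 of these were shared with limma. Control values of many risen genes were near the lowest entry of 1 read, so their ratios depend on the pseudocount: with a pseudocount of 10, Rtp4 had 4.46, Ifit3 3.91 and Marco 3.75. The same holds for falls with OHT values near that entry. With a pseudocount of 10, Lct had -2.40, Lcn4 -1.90 and Slc44a4 -1.64, while Epx, with higher values, had -3.65. Bpifc then had -2.66 and lost its call (limma adjusted p = 0.057).

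Interferon response genes formed the group with the largest change. Of 20 tested members 14 rose and none fell (20 adjusted over the list alone), and the median log2 ratio over the list was 3.17. Examples beside those above are the chemokine Cxcl10 (4.09 ± 0.73), Oas2 (3.29 ± 0.56), the ubiquitin-like modifier Isg15 (2.95 ± 0.47) and the RNA sensor Ddx58, or RIG-I (1.75 ± 0.18). The list as a whole was called up by limma's camera test (adjusted p = 7.8e-11; adjusted p = 0.59 with an estimated correlation).

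Monocyte, macrophage and dendritic cell genes also included rises. Of 28 tested members 11 rose, 0 fell and 17 did not pass (18 rose adjusted over the list alone). Those that rose include the integrin Itgax, or CD11c (3.95 ± 0.54), the mannose receptor Mrc1 (3.64 ± 0.67), the MHC class II chain H2-Eb1 (3.63 ± 0.73) and the CSF1 receptor Csf1r (2.34 ± 0.41), whose mean value went from 524 to 2665. The list median was 1.13 (camera in limma, adjusted p = 1.7e-06; adjusted p = 0.59 with an estimated correlation). Markers of other cell types had smaller medians. Erythroid and megakaryocyte genes had a median of 0.90 over 14 tested members, of which 3 rose and 0 fell (5 and 0 adjusted over the list alone). All 3 are platelet genes: Vwf (2.09 ± 0.36), Gp9 (1.86 ± 0.27) and Gp5 (1.74 ± 0.32). Camera in limma called this list up (adjusted p = 0.033; adjusted p = 0.59 with an estimated correlation), and the call ended with centred ratios (0.051), without the MLL-AF9 pair (0.13) and without transcripts over 0.5 reads per base, where the list median was -0.20 (0.46). Mast cell, basophil and eosinophil genes split. Mcpt2, a mast cell protease, rose (0.87 ± 0.18), whereas the eosinophil granule genes Epx and Prg3 (-1.93 ± 0.37) fell, and the other 17 of 20 tested members did not pass (1 rose and 2 fell adjusted over the list alone). The median was 0.62 (camera in limma, adjusted p = 0.039; adjusted p = 0.59 with an estimated correlation), and the test turned to down at a median of 0.078 when transcripts over 0.5 reads per base were left out. Its call also ended with centred ratios (0.063) and without the PML-RARa pair (0.083).

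Genes of the other lineages gave no list call by limma's camera test. Neutrophil granule and maturation genes had a median of -0.41 (adjusted p = 0.14, 0.0035 without the MLL-AF9 pair), and of 23 tested members Padi4 fell (-1.01 ± 0.12; 1 adjusted over the list alone) and none rose. B, T and NK cell genes had a median of 0.68 (camera in limma, adjusted p = 0.63): of 7 tested members the adaptor gene Blnk rose (4.64 ± 0.65) and the cytotoxic granule gene Nkg7 fell (-2.13 ± 0.22), with 2 rises and 1 fall adjusted over the list alone. Stromal, endothelial and epithelial genes had a median of 0.18 (camera in limma, adjusted p = 0.51), and of 10 tested members the VEGF receptor gene Kdr (3.76 ± 0.82) and Acta2 (0.82 ± 0.17) rose and none fell (3 and 1 adjusted over the list alone). Among 21 tested haematopoietic stem and progenitor genes, Tek, the angiopoietin receptor, rose (1.30 ± 0.29), and the transcription factor genes Erg (-1.01 ± 0.13) and Cebpa (-0.72 ± 0.13) fell (1 and 3 adjusted over the list alone). That list had a median of 0.15 but a mean of -0.0019 (camera in limma, direction up, adjusted p = 0.95). The HOX/MEIS leukaemia programme had a median of -0.53 (camera in limma, adjusted p = 0.24), and of 18 tested members Myb, a transcription factor of proliferating progenitors, fell (-1.89 ± 0.21; 1 adjusted over the list alone) and none rose.

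Proliferation genes included 16 that fell. Of 28 tested members 12 did not pass and none rose (23 fell and 1 rose adjusted over the list alone), and the median log2 ratio was -1.16 (camera in limma, adjusted p = 2.1e-07; adjusted p = 0.59 with an estimated correlation). Beside Birc5 these include the mitotic kinase gene Aurkb (-1.78 ± 0.26), the transcription factor gene Foxm1 (-1.60 ± 0.26) and Top2a (-1.16 ± 0.21), whose mean value went from 3928 to 1801. The D-type cyclins did not pass, and Ccnd1 had the value 2.25 ± 0.79 (limma adjusted p = 0.11). Ribosome biogenesis genes had a median of -0.44; of 23 tested members 4 fell and none rose (11 and 0 adjusted over the list alone), namely Wdr12 (-1.25 ± 0.22), Polr1b (-0.91 ± 0.17), Dkc1 (-0.74 ± 0.16) and Nop56 (-0.69 ± 0.15). Camera in limma called the list down (adjusted p = 2.0e-04; adjusted p = 0.64 with an estimated correlation). Cholesterol synthesis genes included 7 that fell. Of 21 tested members the other 14 did not pass (13 fell and 0 rose adjusted over the list alone). Those that fell include Fdps (-1.78 ± 0.18) and Acat2 (-1.13 ± 0.10). Their list median was -0.44 (camera in limma, adjusted p = 5.0e-05; adjusted p = 0.59 with an estimated correlation).

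Targets of p53 included 6 that rose, while the other 14 of 20 tested members did not pass (12 rose and 0 fell adjusted over the list alone): Zmat3 (1.56 ± 0.19), Phlda3 (1.55 ± 0.25), the death receptor gene Fas (1.0 ± 0.14), Ccng1 (0.85 ± 0.11), Mdm2, whose product degrades p53 (0.63 ± 0.12), and the pro-apoptotic Bax (0.52 ± 0.11). The list median was 0.56 (camera in limma, adjusted p = 5.0e-05; adjusted p = 0.59 with an estimated correlation). In the BCL2 family 3 of 15 tested members rose and none fell (3 and 0 adjusted over the list alone): the anti-apoptotic Bcl2a1b (2.53 ± 0.49) and Bcl2l1 (0.89 ± 0.12), and Bax. Their median was 0.42 (camera in limma, adjusted p = 0.013; adjusted p = 0.59 with an estimated correlation), and that call ended without the MLL-AF9 pair (0.057) and without transcripts over 0.5 reads per base (0.11). Bcl2a1b has near-identical neighbours, among which reads can be split. Among 6 tested inhibitors of cyclin-dependent kinases Cdkn2d fell (-0.54 ± 0.11) and none rose (1 and 1 adjusted over the list alone), and the list had a median of -0.19, a mean of 0.06 and the direction down by camera in limma (adjusted p = 0.91).

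Polycomb genes themselves included 6 that fell, among them Ring1, which the labels give as knocked out. Of 17 tested PRC1 subunit genes Ring1, L3mbtl2 (-0.73 ± 0.16) and Pcgf6 (-0.72 ± 0.15) fell and none rose (5 and 1 adjusted over the list alone). Of 10 tested PRC2 subunit genes, the accessory subunit genes Phf19 (-1.42 ± 0.26) and Mtf2 (-1.20 ± 0.25) and the core subunit gene Suz12 (-0.82 ± 0.17) fell and none rose (4 and 0 adjusted over the list alone). Neither list was called by camera in limma: the PRC1 median was -0.32 (adjusted p = 0.11, and 0.045 without the NT pair) and the PRC2 median -0.39 (adjusted p = 0.089).

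Of the gene groups that PRC1 is known to repress, the developmental transcription factors outside blood were called up by camera in limma (adjusted p = 0.039; adjusted p = 0.79 with an estimated correlation). Their median was 1.15 over 20 tested members, of which Lhx2 (3.68 ± 0.82) and Foxc1 (3.03 ± 0.29) rose and none fell (1 and 0 adjusted over the list alone). The contexts differed in size and sign, with medians of 3.26 in NT, 2.57 in MLL-AF9, 0.02 in HOXA9 and -1.27 in PML-RARa, and the call ended without the NT pair (0.27), without the MLL-AF9 pair (0.24), with a pseudocount of 10 (0.095) and with centred ratios (0.065). Hox genes had a median of -0.39 with 0 of 15 tested members past the test (0 adjusted over the list alone; camera in limma, adjusted p = 0.70). Of 4 tested germline and meiosis genes Stag3, a meiotic cohesin subunit, fell (-0.99 ± 0.11; 1 adjusted over the list alone) and none rose, with a median of 0.03, a mean of -0.11 and the direction down (camera in limma, adjusted p = 0.62). The 5 tested genes represented in the introduced constructs (Hoxa9, Kmt2a, Mllt3, Pml and Rara) had a median of 0.12, a mean of -0.30 and the direction down (camera in limma, adjusted p = 0.72), and none passed (0 rose and 1 fell adjusted over the list alone). No list was called with an estimated correlation or by the fry test.

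**Figure D2:**
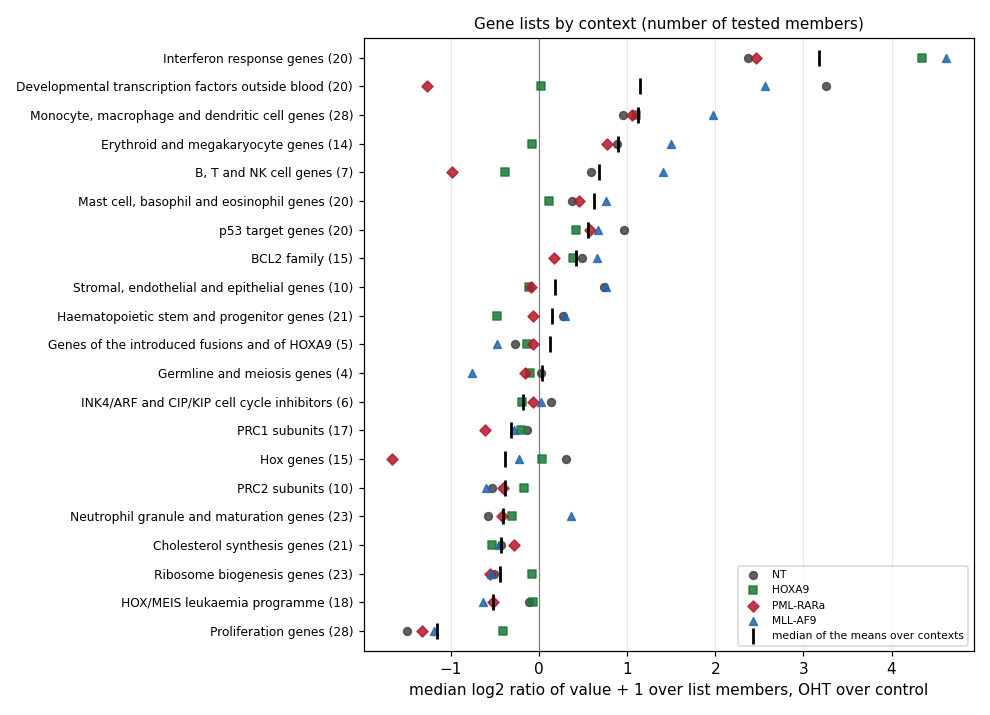
Median log2 ratio of value + 1, OHT over control, of each gene list in each context (coloured points), with the median of the members' means over the 4 contexts (black mark) and the number of tested members in brackets. Interferon response genes lie highest (3.17) and proliferation genes lowest (-1.16), and the developmental transcription factors spread from -1.27 in PML-RARa to 3.26 in NT.

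The 3 transduced contexts were then taken alone, to ask which transcripts changed with OHT in cells that carry an oncogene. These pairs are part of the fit over the 4 contexts, so the results are not independent of each other. Among transcripts past the test, Ccl12 (6.06 ± 0.19, mean log2 ratio ± SE over 3 contexts), Ifit1 (6.05 ± 0.35) and C1qa (6.01 ± 0.28) rose most. Next came Rsad2 (5.95 ± 0.40) and Mertk, a receptor with which macrophages take up dying cells (5.42 ± 0.31). Ttc21a (-3.37 ± 0.21) and the non-coding transcript Gm10560 (-2.60 ± 0.17) fell. These are from 26 transcripts past the test, 24 higher and 2 lower, of 10599 tested by limma (adjusted p between 0.048 and 0.050 for those named; 3196 at an unadjusted p under 0.05). The count is 0 without the HOXA9 or the MLL-AF9 pair, 14 without the PML-RARa pair and 0 with no filter on low values, while edgeR called 534 and DESeq2 1955. On simulated data, with the same change in each context, this fit recovered 25% of 2-fold and 99% of 4-fold changes. These shares do not apply to changes that differ between contexts. Some larger mean rises did not pass, such as that of Atp6v0d2 (6.95 ± 0.56, limma adjusted p = 0.059).

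Whether the change with OHT differed between NT and the transduced contexts was tested as the difference of the log2 ratios. No transcript passed by limma (0 of 10599, with 573 at an unadjusted p under 0.05) or by edgeR (0), and DESeq2 called 64. The 5 transcripts with the smallest p on the side of NT were Map1b (3.91), Tmem198 (3.68), Gm1673 (2.87), Htra3 (3.38) and Dagla (3.75), and on the side of the transduced contexts P2ry13 (-3.07), Rgs13 (-3.34), Ccl12 (-3.82), Cxcl10 (-3.63) and Slc6a12 (-3.79), given as NT minus transduced (limma adjusted p = 0.70 for each). Map1b, a microtubule-binding protein gene, had a ratio of 3.47 in NT against -0.22 in HOXA9, -0.34 in PML-RARa and -0.77 in MLL-AF9. With the lone NT pair against 3 others this test has little power: on simulated data it recovered 0% of 2-fold and 1% of 4-fold changes. Among the gene lists, camera in limma gave a smaller rise in NT for interferon response genes (adjusted p = 8.1e-09) and for monocyte, macrophage and dendritic cell genes (4.7e-05), each with adjusted p = 0.83 with an estimated correlation. The transduced contexts were not alike here: the interferon median was 2.37 in NT and 2.46 in PML-RARa, against 4.34 in HOXA9 and 4.62 in MLL-AF9, and the monocyte median was 0.96 in NT, 1.06 in PML-RARa, 1.10 in HOXA9 and 1.98 in MLL-AF9. These are over the members tested across the contexts. Over the members with a mean value of at least 20 in each pair the interferon median was 2.18 in NT and 3.04 in PML-RARa. The distance between NT and PML-RARa thus depends on which members are taken. Control levels differed too. Against the NT control library, monocyte genes had medians of -0.08 in HOXA9, -0.64 in PML-RARa and -0.81 in MLL-AF9. Interferon genes had -0.04, -0.79 and -0.29 in the same order. A smaller ratio in NT can come from a higher control level, which was not separated from a weaker response.

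Within each context the pair of libraries was compared by size alone, with no replicate check. In NT, 1465 of 10826 transcripts with a value of at least 20 in the higher library were at least 2-fold higher with OHT and 935 were at least 2-fold lower. The highest ratios belonged to the neuronal pentraxin gene Nptx1 (0.827 to 107), Spock2 (1.65 to 149), the transcription factor genes Zic2 (1.65 to 119), Foxf2 (2.48 to 134) and Tbx15 (4.14 to 176), Asphd2 (3.31 to 139), Sel1l3 (24.0 to 808) and Marco (14.1 to 451). Lowest were Glt1d1 (156 to 4.16), Siglecg (266 to 9.35), Ttc21a (343 to 12.5), Epx, Tmc7, Lin28a (570.0 to 31.2), the ficolin gene Fcnb (900.1 to 49.9) and Slc28a2 (498 to 28.0). The median log2 ratio was 3.48 for developmental transcription factors and 2.18 for interferon response genes, each above all of 10000 random lists matched on expression (percentile 100), and -1.50 for proliferation genes (percentile 0). The developmental median is over 10 members with a mean value of at least 20 in this pair, and it was 2.5 over 26 members with a minimum of 5 (percentile 100). Developmental genes near the lowest entry in the control library reach either minimum only if the OHT library is high. This favours risen members, so the developmental percentile does not test for a rise. Beside a monocyte median of 0.98 (percentile 100), erythroid and megakaryocyte genes had 0.81 (percentile 100) and stromal, endothelial and epithelial genes 0.73 (percentile 97.1). B, T and NK cell genes had 0.59 (percentile 93.0) and mast cell, basophil and eosinophil genes 0.39 (percentile 98.9). At a minimum of 5 the erythroid and megakaryocyte median was 0.39 (percentile 97.6) and the B, T and NK median 0.18 (percentile 68.0). The stromal median was then 0.78 and the mast cell median 0.38. The authors' deposited table gives 564 transcripts a p-value under 0.05, and 0 after Benjamini-Hochberg adjustment.

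In HOXA9 cells the difference was smaller by count, with 984 of 10884 transcripts at least 2-fold higher and 664 at least 2-fold lower. The highest ratios belonged to Ccl8 (0.83 to 447), Rtp4 (1.66 to 634), Ifit3 (1.66 to 437), Oasl1 (1.66 to 338), the growth factor gene Pdgfc (0.83 to 229.8), Siglec1 (8.30 to 1012), Atp6v0d2 (12.5 to 1325) and Cd5l, a protein secreted by macrophages (0.83 to 152). Among the lowest were the tight junction gene Cldn11 (286 to 3.62), Lct (114 to 1.81), Bpifc (1006 to 31.7), the incretin receptor gene Gipr (299.7 to 13.6), Epx, Ak5 and Adm (318 to 17.2). Interferon response genes had a median of 4.34 and monocyte genes one of 1.15 (percentile 100 each), against 0.08 for mast cell, basophil and eosinophil genes (percentile 77), -0.12 for stromal, endothelial and epithelial genes (percentile 31.7), -0.18 for erythroid and megakaryocyte genes (percentile 16.5) and -0.38 for B, T and NK cell genes (percentile 12.7). The 22 developmental transcription factors with a mean value of at least 20 in this pair had a median of -0.49 (percentile 0.52). The 20 members tested across the contexts had a median of 0.02 in the same pair, so the sign depends on which members are taken. Proliferation genes had a median of -0.41 (percentile 0) and stem and progenitor genes -0.55 (percentile 0.03). The authors' deposited table has a p-value under 0.05 for 352 transcripts, and for 51 after Benjamini-Hochberg adjustment.

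PML-RARa cells had more transcripts lower than higher with OHT, 1481 against 968 of 10959 by at least 2-fold. Highest were Ccl8 (2.87 to 294), Ccl12 (2.87 to 269), Mrgpra6 (0.957 to 113), Atp6v0d2 (11.5 to 709), C1qa (5.74 to 268), Rsad2, Ifit1 (3.83 to 184) and Tnfsf4, the OX40 ligand gene (2.87 to 146). Lowest were Gipr (657 to 13.1), the receptor kinase gene Insrr (131 to 2.38), Tnfaip6 (277 to 13.1), Syne4 (228 to 10.7), Atp7b (157 to 7.14), Foxd4 (110 to 4.76), Myct1 (130.1 to 5.95) and Epx. Interferon response genes had a median of 3.04 and monocyte genes one of 1.06 (percentile 100 each). The interferon median is over 18 members, and it was 2.32 over 22 members with a minimum mean value of 5 (percentile 100). Erythroid and megakaryocyte genes had 0.77 (percentile 99.99) and mast cell, basophil and eosinophil genes 0.47 (percentile 99.95). Stromal, endothelial and epithelial genes had -0.23 (percentile 22.5) and B, T and NK cell genes -1.22 (percentile 0.34). At a minimum mean value of 5 the erythroid and megakaryocyte median turned to -0.23 (percentile 26.11). The B, T and NK median was then 0.02 (percentile 72.35), the mast cell median 0.48 and the stromal median -0.23. In this pair Hox genes (-1.53, percentile 0) and developmental transcription factors (-1.25, percentile 0.01) lay lower with OHT. Members near the lowest entry with OHT enter only if the control library is high. This favours fallen members, so the Hox and developmental percentiles do not test for a fall. With a minimum mean value of 5 in place of 20 the Hox and developmental medians were -1.24 (percentile 0) and -0.68 (percentile 0.29). The Hox median depended on that minimum in the other contexts, with 1.15 in NT (percentile 99.9) and 0.75 in MLL-AF9 (percentile 99.9) at 5, against -0.41 (percentile 12.5) and -0.17 (percentile 53.7) at 20, and in HOXA9 it was -0.04 and 0.03. The authors' deposited table gives 449 transcripts a p-value under 0.05, of which 5 remain after Benjamini-Hochberg adjustment.

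MLL-AF9 cells showed the highest counts, with 1570 of 10831 transcripts at least 2-fold higher and 1694 at least 2-fold lower. All ratios of this pair had a median of -0.12, and centring on the median moved the share of higher transcripts from 48.1% to 55.6%, so which direction prevails depends on the scaling. The highest ratios were those of Atp6v0d2 (2.12 to 1052), Marco (1.06 to 679), Irg1, a mitochondrial enzyme gene of activated macrophages (4.24 to 1640), the chemokine Ccl7 (3.18 to 1228), Ifit3 (1.06 to 543), Fabp4 (1.06 to 480.2), Rtp4 (2.12 to 690.3) and the lipid exporter gene Abca1 (3.18 to 881). Lowest were the cytokine gene Tgfb2 (391 to 4.09), Megf10 (357 to 6.82), Lct, Cldn11 (329 to 12.3), 4930428O21Rik, Cth (739 to 34.1), Otogl and Fgf23 (151 to 8.19). Interferon response genes had a median of 4.18, developmental transcription factors 3.53 and monocyte genes 1.98 (percentile 100 each). The developmental median, over 14 members, was 2.53 over 26 members with a minimum mean value of 5 (percentile 100). Here too, members near the lowest entry in the control library enter only if the OHT library is high, so this percentile does not test for a rise. As in NT, markers of other cell types had medians above 0 in this pair, with 1.5 for erythroid and megakaryocyte genes (percentile 99.97), 1.41 for B, T and NK cell genes (percentile 99.0), 0.81 for stromal, endothelial and epithelial genes (percentile 96.6) and 0.69 for mast cell, basophil and eosinophil genes (percentile 99.8). Neutrophil genes had a median of 0.36 (percentile 99.5), against -0.58 in NT (percentile 0), -0.30 in HOXA9 (percentile 0) and -0.41 in PML-RARa (percentile 0.53). In the authors' deposited table the p-value is under 0.05 for 806 transcripts, and for 164 after Benjamini-Hochberg adjustment.

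The contexts resembled each other to different degrees. Across 10599 transcripts, which are not independent replicates, Pearson's r between the log2 ratios was 0.71 for HOXA9 with MLL-AF9, 0.64 for NT with MLL-AF9, 0.63 for HOXA9 with PML-RARa, 0.49 for PML-RARa with MLL-AF9, 0.48 for NT with PML-RARa and 0.42 for NT with HOXA9. No library is shared between contexts. Of the transcripts at least 2-fold higher, 712 were common to NT and MLL-AF9, where lists independent of each other would share 146, and 652 to HOXA9 and MLL-AF9 (109 for independent lists). Of those at least 2-fold lower, 582 were common to PML-RARa and MLL-AF9 (168 for independent lists) and 147 to NT and HOXA9 (37.1).

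The control libraries themselves differed between contexts, and with these libraries the introduced gene cannot be separated from the transduction or from the single library. Against the NT control library, 1257 transcripts were at least 2-fold higher and 794 lower in HOXA9, 1352 and 905 in PML-RARa, and 923 and 1154 in MLL-AF9, each from 1 library per group. The tested Hox genes were higher in all 3, with medians of 2.16 in HOXA9, 1.64 in PML-RARa and 2.84 in MLL-AF9 on the log2 scale. The HOX/MEIS programme had its highest median in MLL-AF9 (2.04, with 13 of 18 members at least 2-fold higher), against 0.69 in HOXA9 and 0.43 in PML-RARa. Mast cell genes were lower in HOXA9 (-2.25) and MLL-AF9 (-3.61) and near NT in PML-RARa (-0.07), and erythroid and megakaryocyte genes had medians of -2.18, -3.30 and -0.53 in the same order. Developmental transcription factors had medians of 3.73 in HOXA9, 5.08 in PML-RARa and 0.98 in MLL-AF9. Their median value was 1.65 in the NT control library, 4.24 in MLL-AF9, 57.7 in HOXA9 and 76.5 in PML-RARa, and with OHT it was 34.8, 66.2, 60.6 and 42.3 in the same order. Members with a value of at least 20 went from 4 to 15 of 20 in NT and from 5 to 16 in MLL-AF9, against 15 to 17 in HOXA9 and 17 to 14 in PML-RARa. A list here holds the members with a mean value of at least 20 over the 8 libraries. These are 15 of 37 measured Hox genes and 20 of 72 measured developmental genes. Most of the libraries are transduced, which favours genes high in transduced cells. The Hox and developmental medians against NT hold for these members only and can be raised by that choice.

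**Figure D3:**
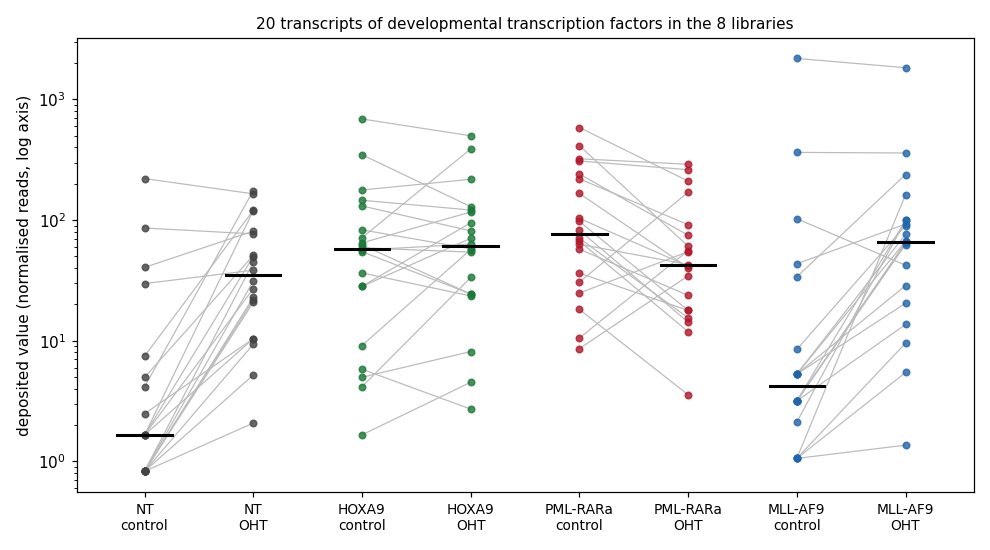
Deposited value (normalised reads, log axis) of the 20 tested transcripts of developmental transcription factors in the 8 libraries; each point is a transcript, grey lines join a transcript's control and OHT values within a context, and black bars are medians. The median went from 1.65 to 34.8 in NT and from 4.24 to 66.2 in MLL-AF9, and was 57.7 and 76.5 in the control libraries of HOXA9 and PML-RARa. The 20 were kept for a mean value of at least 20 over the 8 libraries, which favours genes high in transduced cells.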

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

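Of the tests, 2 for the macrophage and interferon pattern were fixed before their results were seen, while the depth test and the tests of the read ceiling and of the developmental genes were chosen after the patterns were seen.

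Interferon response genes (camera in limma, adjusted p = 8.1e-09) and monocyte, macrophage and dendritic cell genes (4.7e-05) had smaller log2 ratios in NT than in the mean of the transduced contexts, and neutrophil genes (3.1e-04) and proliferation genes (5.2e-04) lay lower in NT. Developmental transcription factors (3.0e-04) and p53 target genes (0.0059) lay higher in NT than in that mean. The developmental rise was not particular to NT, with medians of 3.26 in NT and 2.57 in MLL-AF9 against 0.02 in HOXA9 and -1.27 in PML-RARa. These 6 lists were singled out because the effect in NT differed from that in the other contexts by the preset-correlation test, and each has adjusted p = 0.83 with an estimated correlation. The list ratios rest on the lone NT pair, and PML-RARa lay close to NT in 4 of these lists, with medians of 2.46 against 2.37 for interferon, 1.06 against 0.96 for monocyte, -0.42 against -0.58 for neutrophil and -1.33 against -1.50 for proliferation genes, so HOXA9 or MLL-AF9 lay farther from NT there. These are over the members tested across the contexts. Over the members of each pair with a mean value of at least 20 the interferon medians were 3.04 and 2.18. Interferon and monocyte genes lay lower in the PML-RARa and MLL-AF9 control libraries than in that of NT, and near NT in HOXA9. A smaller ratio in NT therefore need not be a weaker response.

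Single transcripts had a log2 ratio of one sign in NT and of the other sign in all 3 transduced contexts, given as the log2 ratio in NT minus the mean of the others: Rnf2 (0.41), Cdkn2a NM_009877 (0.80), Map1b (3.91), Tmem198 (3.68), Gm1673 (2.87), Htra3 (3.38), P2ry13 (-3.07), Rgs13 (-3.34) and Slc6a12 (-3.79). None of these differences passed the limma test after adjustment. For Rgs13 the libraries of HOXA9 and MLL-AF9 all stood at the lowest entry of 1 read, so its signs there show no change, and the Rnf2 ratio in MLL-AF9 was -0.0058, or 0.12 with centred ratios.

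The rise of macrophage and interferon genes with OHT may reflect a change in the makeup of the cultures or a change within cells. A lower share of progenitors that raises every other cell type alike is argued against, since the median of monocyte genes exceeded that of 51 mast cell, lymphoid, erythroid and stromal genes by 0.73 (SE 0.17 over 4 contexts, 0.36 in NT); the other types had medians of 0.59 in NT, 0.45 in PML-RARa, 1.17 in MLL-AF9 and -0.04 in HOXA9, so a lower share of progenitors may still be part of it, as may more macrophages. The lower depth of the OHT libraries is argued against by the HOXA9 pair, with nearly equal read totals (6657911 and 6641843) and size factors of 1.20 and 1.11, where both lists together had a median of 2.17. An effect of OHT itself cannot be told apart from loss of Ring1b, because no OHT library labelled wild type is among the 8. Under such an effect the cholesterol genes were predicted as possibly higher. Their mean list median was -0.42, in the other direction. No value among these libraries can exclude an effect of the compound. Loss of Ring1b thus stays open beside OHT and a changed cell makeup.

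Read counts level off below 2 per base of transcript. One candidate explanation is that repeat reads at a position were counted once per strand. It stays open, since the 0.0053% of transcripts over 2 reads per base in any library are the pattern itself and decide nothing. Whether the number of reads sequenced sets the limit stays open too: between the shallowest and the deepest library the median read ratio of transcripts over 1 read per base was higher by 0.325 than the 0.5 of 5958 less densely covered transcripts, but these libraries also differ in context and treatment. No biological explanation was tested for this pattern.

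The tested developmental transcription factor genes, 20 of 72 measured, were already expressed in the HOXA9 and PML-RARa control libraries. They were kept for their mean value over all libraries, which favours genes high in transduced cells. Swapped labels within those pairs are argued against, since the lower of their interferon list medians was 2.46, in the same direction as in NT and MLL-AF9. Control cells that already carried the whole OHT response are argued against as well, since the higher median of interferon and monocyte genes against the NT control library was -0.067. An effect of the introduced HOXA9 and PML-RARa, or an earlier loss of repression at these genes alone, may explain the levels and was not tested.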

How the results depend on the processing

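Among the settings given here, edgeR without each pair, the NT and MLL-AF9 pairs alone, the exclusion of transcripts over 0.5 reads per base, the minimum of 100 between control libraries and the restriction of the splits to those that part all pairs were added after seeing the data. The main limits are the 4 pairs, the 1 library per group and the reads near the lowest entry.

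Across the 4 contexts limma called 1471 transcripts. The count was 354 with no filter on low values, 2314 with a mean-variance trend, 2235 by edgeR, 3130 by DESeq2 and 420 when all 4 ratios had to share a sign and reach 2-fold with no test. Without each pair in turn it ranged from 0 to 26 by limma and from 0 to 534 by edgeR, and it was 0 for the NT and MLL-AF9 pairs alone. edgeR called 534 without NT and 512 without HOXA9 but 0 without PML-RARa or MLL-AF9, so the number of pairs alone does not account for the loss, and its cause was not tested. Without the block the count was 999, and the other 9 settings gave 1060 to 2157. In the transduced contexts the 26 calls became 16 with a pseudocount of 0.5, 0 with no filter, 72 with a minimum of 100, 358 with the trend, 534 by edgeR, 1955 by DESeq2 and 0 to 14 without each pair. For NT against the transduced contexts DESeq2 gave 64 and the 8 other settings 0.

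At least 2-fold differences within NT, HOXA9, PML-RARa and MLL-AF9 (2400, 1648, 2449 and 3264) became 1272, 770, 1208 and 1734 at 3-fold, 1429, 932, 1429 and 1982 with a minimum of 100, and 4096, 3033, 3996 and 5077 with no minimum, by the construction of each setting. By adjusted p in the authors' deposited table they were 0, 51, 5 and 164. Between control libraries and NT the totals of 2051, 2257 and 2077 in HOXA9, PML-RARa and MLL-AF9 became 1107, 1252 and 1090 with a minimum of 100.

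Of the gene lists, 10 were called at the preset correlation, 0 with an estimated correlation and 0 by fry. Over all lists and settings 196 results were the same, 31 lost their call, 2 gained one and 1 turned: the mast cell, basophil and eosinophil list had a median of 0.078 and the direction down without transcripts over 0.5 reads per base, which leaves 6 members. Named transcripts in a test gave 680 same, 289 without their call, 5 with a gained call and 0 turned. Where no cause is given, the cause was not tested.

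Other splits of the 8 libraries into 4 and 4 were fitted where the block allowed it (32 of 35). The libraries are paired by context, and 8 of these splits part all 4 pairs as the real one does, which is too few for a share under 0.05. Of the 8 splits the real one was the 1 with as many limma calls (1471, highest other 0), edgeR calls (2235, highest other 0) and called lists (10, highest other 9). The other 24 splits part 2 pairs and keep the difference with OHT of the remaining pairs as spread; they gave at most 1 limma call, 0 edgeR calls and 12 called lists. With 10 splits of 3 and 3 in the transduced contexts (1 as large, 26 against 0 for the others) a share under 0.05 cannot be had.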

Other observations

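Several single genes outside the developmental list, chosen after their values were seen, had log2 ratios over 2 in NT and MLL-AF9 and under 1 elsewhere. Cyclin D1 (Ccnd1) had log2 ratios of 3.84 in NT and 4.07 in MLL-AF9 against 0.24 in HOXA9 and 0.85 in PML-RARa. The cell cycle inhibitor gene Cdkn2b, a neighbour of Cdkn2a, had 2.36 and 2.09 against 0.18 and 0.40. The stem cell receptor gene Procr had 3.04 and 4.64 against 0.34 and -0.41, and Hoxd13 had 3.98 and 3.49 against -0.50 and -3.03. None of these passed the limma test across the 4 contexts (adjusted p = 0.11 for Ccnd1, 0.12 for Cdkn2b, 0.21 for Procr and 0.61 for Hoxd13).

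Other genes, likewise chosen after their values were seen, had their largest ratio in MLL-AF9 and their smallest in NT or PML-RARa. The platelet chemokine genes Ppbp (0.85 in NT, 3.32 in HOXA9, 3.32 in PML-RARa and 6.79 in MLL-AF9) and Pf4 (0.91, 2.46, 2.15 and 4.2) were higher with OHT in all 4 contexts, as were the interleukin 7 receptor gene Il7r (1.99, 4.82, 2.37 and 7.30) and the kinase gene Plk2 (2.82, 2.85, 0.88 and 6.87). Their means did not pass the limma test (adjusted p = 0.069 for Ppbp, 0.051 for Pf4, 0.056 for Il7r and 0.081 for Plk2).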
